A study of Mus musculus with 16 samples.

How the data were processed

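Chromatin immunoprecipitation followed by sequencing (ChIP-seq), which counts the DNA fragments bound by a protein along the genome, was done in 3T3-L1 adipocytes. 3T3-L1 is a mouse fibroblast line that turns into fat cells in culture. Per the labels, the cells were at day 7 of differentiation and had received 1 µM rosiglitazone or 0.1% DMSO, its solvent, for 1 h. The 16 samples fall into 12 groups of antibody and treatment. PPARγ and RNA polymerase II have 2 samples per treatment in the labels, and C/EBPα, MED1, CBP and input chromatin have 1 per treatment.

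The files used here are a PPARγ peak list and a C/EBPα peak list. Per the submitters' processing notes, FastQC, Bowtie, HOMER and edgeR were used and the genome build was mm9. Their versions and settings are not given in the sources used here. Each list gives peak positions and, in 8 columns, a normalised tag signal for PPARγ, C/EBPα, MED1 and CBP in each treatment, as deposited by the authors. A tag is the mapped read of 1 fragment. The MED1 rosiglitazone column is headed BRL, a development code of that drug, and was assigned to the only MED1 sample with rosiglitazone. The PPARγ columns name no replicate, so each was taken as 1 PPARγ library of its treatment, and whether it holds 1 or both labelled samples is not known. RNA polymerase II and input chromatin were not analysed here.

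Each list also carries a peak score, deposited by the authors with 1 value per peak. Divided by the tags of both treatments pooled and scaled to 10 M (mega), this score had a median of 0.998 in the PPARγ list and 0.998 in the C/EBPα list. The 5th and 95th percentiles were 0.882 and 1.10 in the PPARγ list and 0.898 and 1.03 in the C/EBPα list. The focus ratio, a fraction per peak that the authors deposited, was used only to describe peaks. Scores were used to rank or describe peaks within a list and, as an alternative, as the measure of height.

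The deposited signal values were whole multiples of a fixed step in every column. With a tolerance of 0.02 steps, 100% of the values above 0 came out whole in all 8 columns of both lists, so tags per peak were recovered. If the values are scaled to 10 M tags, the HOMER default, which no file header states, the steps correspond to 11.4 M tags for PPARγ in DMSO and 12.0 M in rosiglitazone. C/EBPα then had 4.53 and 7.85 M, MED1 2.86 and 1.31 M, and CBP 4.52 and 1.65 M. Ratios between treatments use the authors' scaling and do not depend on that assumption, while the absolute depths do. MED1 and CBP were therefore 2.19 and 2.74 times deeper in DMSO, and C/EBPα was 1.73 times deeper in rosiglitazone.

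Peaks were called shared when they had at least 1 bp in common. The shared count was set against 1000 circular shifts of the C/EBPα peaks within each chromosome, a one-sided test whose smallest p is 0.001. Peak height was the mean of the deposited values of the peak's own factor in both treatments. Median heights were compared by a two-sided permutation test with 100000 permutations over peaks and a bootstrap interval from 500 resamples. Peaks are not independent replicates, so these p-values describe the lists. Clustering was the share of peaks with a neighbour of the same list within 10 kb, against 1000 uniform placements of the same number of peaks on each chromosome, with clusters of at least 5 peaks counted.

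Each factor has 1 column per treatment, so differences between treatments have no replicate check and no p-value is given for them. Values of 2 kinds are reported instead. The first is the log2 ratio of rosiglitazone to DMSO per peak with a pseudocount of 1, which understates the change of low peaks, with counts of peaks that differ at least 2-fold. The second is the ratio of tags summed over a class of peaks, with an exact 95% interval from the binomial distribution of the tags (Clopper-Pearson). Tags carry no molecular identifiers, so every such interval covers counting error only and not the spread between cultures. Where a library held 0 tags, the fold was computed against 3 tags in that library and written as at least that fold. The bound of the exact 95% interval is weaker and is given beside it.

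Several analyses were added after the values had been seen. Classes of sites were compared at equal total tags by a Mantel-Haenszel odds ratio over strata of total tags, with a bootstrap interval over peaks. Tags were thinned at random to the depth of the shallower library. Counting noise was simulated 100 times with 1 common ratio for all peaks. A binomial test per peak with Benjamini-Hochberg adjustment at 0.05 compared the tags of the 2 libraries of a factor. That test compares those libraries, not the conditions, and stands in for a count model, which needs replicates. Regions of 1 Mb with at least 5 unshared peaks of a list were marked as high background by the other factor's tags. The median of these tags at such peaks had to be at least 3 times the genome median. The mitochondrial chromosome was marked as well, without that rule.

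The functions were tested on simulated data with known answers. Tags drawn at 30588 PPARγ peaks were recovered from rounded values for 100% of peaks. A simulated common PPARγ ratio of 1.5 was estimated as 1.50 (1.49 to 1.50) over 30388 unchanged peaks. In that simulation the test of 2 libraries called 64.0% of 50 peaks that were 4-fold higher and 18.0% of 50 peaks that were 2-fold higher, so it misses most 2-fold changes. For MED1 it called 72.0% and 6.00%. A simulated MED1 odds ratio of 1.3 was estimated as 1.31 (1.28 to 1.33), and one of 1 as 1.00 (0.985 to 1.02). The 95% interval of single PPARγ peaks held the true ratio in 96.8% of 26384 peaks. A single random placement proved too noisy to judge the overlap, so 40 were averaged: the overlap was 1.01 times the mean of the shifts, and 3 of the 40 had p under 0.05.

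The peaks named in the text follow a rule fixed before the data were examined. It takes the 10 peaks of each list with the highest score, the 10 largest increases and 10 largest decreases past 2-fold among peaks with at least 20 tags in the higher library, and the 5 clusters with the most peaks. The rule also covered members of 15 gene lists. These were not used, because the gene annotation at hand is of another build (GRCm38) than the peaks (mm9), and coordinates were not converted. No peak is therefore assigned to a gene, an exon or an intron, and the planned comparison of peaks near gene lists was not run. Counts of peaks at least 2-fold higher or lower were first made with at least 20 tags and then, as planned before the data were examined, over all peaks, and both are given. The alternatives tried were other definitions of a shared peak, stronger subsets of each list, another pseudocount, minimum tags, other scalings, and other distances for clustering. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. All positions are in mm9 as deposited.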

Results

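The series examined where PPARγ, C/EBPα and the coactivators MED1 and CBP sit in fat cell chromatin, and what 1 h of rosiglitazone does to their occupancy. PPARγ is the nuclear receptor that drives fat cell differentiation and is the target of rosiglitazone, an antidiabetic drug. C/EBPα is a transcription factor that acts with PPARγ in fat cells. MED1 is the subunit of the Mediator complex that binds nuclear receptors, and CBP is a histone acetyltransferase. The PPARγ list held 30588 peaks and the C/EBPα list 30519. Median tags per PPARγ peak were 12 in the DMSO library and 17 in the rosiglitazone library, and C/EBPα peaks held 7 and 13 C/EBPα tags. MED1 and CBP were shallow, with a median of 2 tags per PPARγ peak in DMSO and 1 in rosiglitazone for both. Single peaks of these coactivators are therefore poorly measured. Sums over many peaks have little counting error, but the enrichment of each library and the spread between cultures stay unmeasured.

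PPARγ and C/EBPα occupied many of the same sites. Of the PPARγ peaks, 11034 (36.1%, 95% interval 35.5 to 36.6) shared sequence with a C/EBPα peak, and 36.2% of the C/EBPα peaks shared sequence with a PPARγ peak. Sharing followed peak strength. In the lowest decile of the PPARγ list by score 18.2% of peaks were shared (16.9 to 19.7), and in the highest decile 68.0% (66.3 to 69.7). The C/EBPα list ran from 18.2% (16.9 to 19.6) to 71.8% (70.2 to 73.4). Shifted C/EBPα peaks overlapped on average 170 PPARγ peaks and at most 226, so the observed count was 64.9 times the mean of the shifts (one-sided permutation by circular shift, p = 0.001, the smallest that 1000 shifts can give). The shifts place peaks anywhere on a chromosome, so this excess includes whatever both factors share by binding open chromatin.

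**Figure D1:**
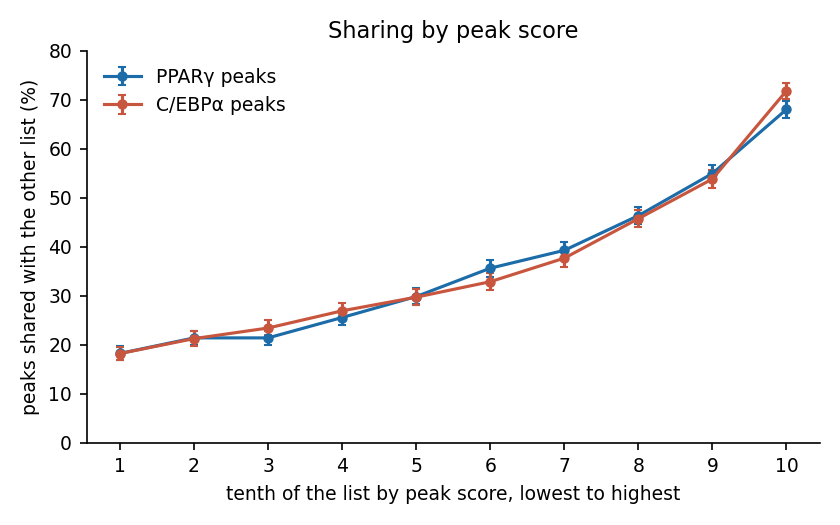
Percent of peaks shared with the other list (vertical axis) for each decile of a list by peak score (horizontal axis, lowest to highest), PPARγ peaks in blue and C/EBPα peaks in red, with exact 95% binomial intervals. Sharing was 18.2% in the lowest decile of both lists, and 68.0% of PPARγ peaks and 71.8% of C/EBPα peaks were shared in the highest.

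Peaks that both factors occupied were higher, which restates the rise of sharing with score because the score nearly equalled the scaled pooled tags. The median PPARγ height was 15.1 deposited units at the 11034 peaks with C/EBPα and 10.5 at the 19554 without it, a difference of 4.62 (4.37 to 4.87). The median C/EBPα height was 21.8 at the 11033 peaks with PPARγ and 14.3 at the 19486 without it, a difference of 7.56 (7.14 to 7.94). Both differences had p = 1e-05 in the permutation test over peaks, the smallest it can give.

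The strongest PPARγ peaks were mostly shared sites. Among the 10 with the highest score, 7 overlapped a C/EBPα peak. The top peak, on chromosome 17 from 39984988 to 39985174 with a score of 875.6, did not. It held 719 units of PPARγ in DMSO and 1041 in rosiglitazone, a ratio of 1.45 (1.32 to 1.58). It was also rich in every other antibody, with 651 and 352 units of C/EBPα, 737 and 872 of MED1, and 146 and 194 of CBP. The rule for high background works on regions of 1 Mb and did not mark it. Whether this peak is an artefact was not tested. The next, on chromosome 2 from 167527747 to 167527933, had a PPARγ ratio of 2.94 (2.53 to 3.42). A peak on chromosome 5 from 64717766 to 64717952 and one on chromosome 7 from 26177004 to 26177190 both had a ratio of 2.57. A peak on chromosome 15 from 99546404 to 99546590 had the highest ratio of the 10, 3.27 (2.78 to 3.87). In contrast, 2 did not differ beyond counting error, on chromosome X from 166435931 to 166436117 with 1.12 (0.982 to 1.27) and on chromosome 10 from 117154738 to 117154924 with 1.01 (0.885 to 1.15). The latter and the peak on chromosome 10 from 117486472 to 117486658, with 2.83 (2.42 to 3.31), lay in high background.

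The strongest C/EBPα peaks lay partly in regions of high background. The top peak lay on chromosome 17 from 39984676 to 39984906, next to the top PPARγ peak, with 6244 C/EBPα units in DMSO and 4858 in rosiglitazone. The next, on chromosome 8 from 24205994 to 24206224, held 4487 and 3597. It also held 1111 and 1534 units of PPARγ, more than the top PPARγ peak, though no listed PPARγ peak overlapped it. MED1 there was 55.9 and 107 units and CBP 28.7 and 6.06. The peak was not marked as high background, and whether it is an artefact was not tested. Of the 10 highest, 6 were shared with PPARγ. High background marked 5, of which 3 lay on chromosome 10 between 117147005 and 117540658, 1 on chromosome 2 and 1 on the mitochondrial chromosome. The last was marked without the rule for regions.

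After 1 h of rosiglitazone, PPARγ tags at PPARγ peaks, scaled as deposited, were higher on every chromosome. Summed over all PPARγ peaks they were 1.53 times the DMSO value (1.52 to 1.53), and the ratio was above 1 on 20 of 20 chromosomes, from 1.35 to 1.73. The highest decile of peaks by score had a ratio of 1.75 (1.74 to 1.76) and the lowest decile 1.38 (1.36 to 1.40). The median log2 ratio per peak was 0.50 (quartiles -0.11 and 1.15). At least 2-fold higher were 9168 of the 30588 peaks and at least 2-fold lower were 1356, where counting noise around the common ratio gave 5857 and 61.3. Among 13333 peaks with at least 20 tags, 5678 were higher and 464 lower. The split depends on the scale. Scaled to the PPARγ ratio of 1.47 at C/EBPα peaks without a PPARγ peak, a log2 shift of 0.55, the counts over all peaks were 4609 higher and 4595 lower. Centred on the median of all peaks they were 4767 and 4089.

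Single PPARγ peaks differed far more than that average. Ordered by log2 ratio with a pseudocount of 1, the first was on chromosome 2 from 170285319 to 170285505, with 0 tags in DMSO and 52 in rosiglitazone, at least 16.4-fold higher against 3 tags (exact 95% lower bound 12.9). A peak on chromosome 8 from 113249230 to 113249416 held 2 tags in DMSO and 120 in rosiglitazone, a ratio of 56.7 (15.4 to 474), and one on chromosome 3 from 51013873 to 51014059 held 1 and 71, a ratio of 67.1 (11.7 to 2688). At the peak on chromosome 8 MED1 was 18.2 times higher (5.57 to 94.4) and CBP 4.99 times (2.28 to 11.5), and the peak was among the 10 with the highest ratios of both coactivators. Of the 10 highest PPARγ ratios, 6 were at peaks shared with C/EBPα, and of the 10 lowest, 0. First among the lowest was one on chromosome 11 from 55046199 to 55046385, with 43 tags in DMSO and 0 in rosiglitazone, at least 15.2-fold lower against 3 tags (exact upper bound of the ratio 0.0847). One on chromosome 2 from 40335894 to 40336080 held 102 tags in DMSO and 3 in rosiglitazone, a ratio of 0.0278 (0.00564 to 0.0836). These peaks held 0 and 1 tags of C/EBPα, MED1 and CBP together, and whether they mark PPARγ occupancy in DMSO or an artefact of that PPARγ library was not tested. With 1 common ratio for all peaks, counting noise alone gave 2622 higher and 4.13 lower among peaks with at least 20 simulated tags, on average over 100 simulations. The test of the tags of the 2 libraries called 6152 peaks higher and 479 lower without rescaling, and 2173 and 2147 around the common ratio of 1.53. How much of this spread lies between cultures cannot be measured with 1 column per treatment.

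**Figure D2:**
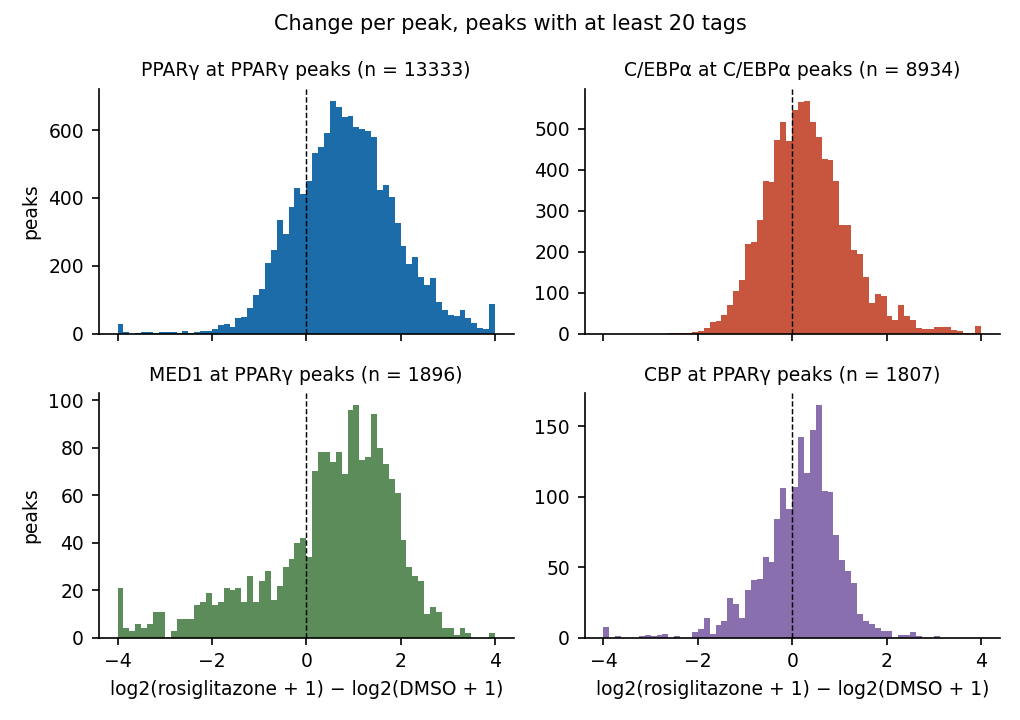
Number of peaks (vertical axis) by log2 ratio of rosiglitazone to DMSO with a pseudocount of 1 (horizontal axis), for peaks with at least 20 tags in the higher library, values past the axis ends being counted in the outermost bars. PPARγ at its own peaks is centred at a median of 0.82 and C/EBPα at its own peaks at 0.25, while MED1 and CBP at PPARγ peaks have medians of 0.78 and 0.26. A peak reaches 20 tags more easily in the deeper library, which was rosiglitazone for C/EBPα and DMSO for MED1 and CBP. These medians are therefore not comparable between factors, and over all C/EBPα peaks the median was 0.07.

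C/EBPα occupancy differed little in total. Summed over its 30519 peaks, C/EBPα tags in rosiglitazone were 1.01 times those in DMSO (1.01 to 1.02), and the ratio was above 1 on 14 of 20 chromosomes. The highest decile of peaks by score had a ratio of 0.950 (0.944 to 0.957), while every other decile lay between 1.03 and 1.07. Over all C/EBPα peaks the median log2 ratio was 0.07 (quartiles -0.50 and 0.71). At least 2-fold higher were 4851 peaks and lower were 2822, where counting noise around the common ratio gave 2195 and 1402. Among 8934 peaks with at least 20 tags, 1670 were higher and 441 lower. After thinning the deeper rosiglitazone library to equal depth this became 714 and 532 of the 4887 peaks that still had 20 tags, and centred on the median of the 8934 peaks, 1140 and 882. By log2 ratio with a pseudocount of 1, the highest was on chromosome 1 from 92938357 to 92938587, with 0 tags in DMSO and 41 in rosiglitazone, at least 7.88-fold higher against 3 tags (exact lower bound 6.13). Among the 8934, the lowest ratio was on chromosome 4 from 109348899 to 109349129, with a ratio of 0.162 (0.0590 to 0.384). The very high peak on chromosome 10 from 117183450 to 117183680 had a ratio of 0.476 (0.439 to 0.516). Counting noise around the common ratio gave 365 higher and 41.8 lower among peaks with at least 20 simulated tags. The test of the 2 libraries called 503 C/EBPα peaks higher and 383 lower, and around the common ratio 482 and 429.

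MED1 tags at PPARγ peaks were higher with rosiglitazone. Summed over all PPARγ peaks the ratio was 1.63 (1.61 to 1.64), above 1 on 20 of 20 chromosomes, from 1.48 to 1.82. The median log2 ratio per peak was 0.00 (quartiles -0.64 and 1.21). Over all peaks 9125 were at least 2-fold higher and 6876 lower, where counting noise around the common ratio gave 8543 and 4194. Among 1896 peaks with at least 20 tags, 796 were higher and 288 lower, and after thinning the deeper DMSO library to equal depth, 754 and 48 of 1106. Centred on the median of the 1896 peaks, 290 were higher and 446 lower. A peak on chromosome 2 from 29377029 to 29377215 had a MED1 ratio of 16.8 (5.07 to 87.3) and one on chromosome 8 from 10960278 to 10960464 had 10.0 (4.34 to 26.9). In contrast, a shared peak on chromosome 1 from 145794143 to 145794329 held 70 MED1 tags in DMSO and 0 in rosiglitazone, at least 10.7-fold lower against 3 tags (exact upper bound of the ratio 0.118), with 51.9 and 54.0 units of PPARγ. Counting noise with no difference gave 8.95 higher and 160 lower among peaks with at least 20 simulated tags. Around the common ratio of 1.63 it gave 275 and 7.84. The test of the 2 libraries called 974 peaks higher and 93 lower, but 163 and 237 around the common ratio.

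CBP tags at PPARγ peaks were also higher with rosiglitazone, by less. The summed ratio was 1.38 (1.37 to 1.39), above 1 on 20 of 20 chromosomes, from 1.27 to 1.52. The median log2 ratio was 0.00 (quartiles -1.01 and 0.90), and 7234 peaks were at least 2-fold higher and 7676 lower, where counting noise gave 6952 and 5314. Among 1807 peaks with at least 20 tags, 207 were higher and 133 lower. With the DMSO library thinned to equal depth, 154 were higher and 4 lower among 429, and centred on the median of the 1807 peaks, 105 and 208. The highest CBP ratio was on chromosome 2 from 101586780 to 101586966, at 9.15 (3.54 to 27.8). A peak on chromosome 4 from 137043479 to 137043665 followed with 6.47 (3.37 to 13.1), with 116 units of PPARγ in DMSO and 377 in rosiglitazone. The lowest was on chromosome 5 from 32438154 to 32438340, with 27 tags in DMSO and 0 in rosiglitazone, at least 3.28-fold lower against 3 tags (exact upper bound of the ratio 0.402). Counting noise with no difference gave 11.9 higher and 173 lower among peaks with at least 20 simulated tags. Around the common ratio of 1.38 it gave 111 and 32.1. The simulated peaks need not be the 1807, so these counts are not strictly comparable with the 207 and 133 seen. The test of the 2 libraries called 128 peaks higher and 1 lower, but 2 and 1 around the common ratio, so CBP differences between single peaks were hardly detected.

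The coactivator tags differed by class of site. MED1 was 1.64 times higher at PPARγ peaks without C/EBPα (1.62 to 1.66), 1.61 times at shared peaks (1.60 to 1.63) and 1.23 times at C/EBPα peaks without PPARγ (1.21 to 1.25). CBP followed the same order, with 1.41 (1.39 to 1.43), 1.36 (1.35 to 1.38) and 1.11 (1.09 to 1.12). PPARγ itself was 1.44 (1.43 to 1.44), 1.63 (1.62 to 1.63) and 1.47 (1.46 to 1.48), so its tags were also higher at C/EBPα peaks where no PPARγ peak was listed. C/EBPα ratios were 0.942 (0.929 to 0.954), 0.994 (0.987 to 1.00) and 1.03 (1.03 to 1.04). At equal total tags, the odds of a tag coming from the rosiglitazone library were higher at PPARγ-only than at C/EBPα-only peaks, by 1.27 for MED1 (1.24 to 1.31) and 1.27 for CBP (1.23 to 1.30). Shared peaks against C/EBPα-only peaks gave 1.20 for CBP (1.17 to 1.23) and 1.12 for MED1 (1.09 to 1.16). For PPARγ itself the odds at equal PPARγ tags went the other way, with 0.870 (0.838 to 0.902) for PPARγ-only and 0.931 (0.893 to 0.973) for shared against C/EBPα-only peaks. For MED1 the value at shared peaks was 1.05 (1.02 to 1.09) when the shared sites were counted in the C/EBPα windows, and 0.982 (0.931 to 1.04) among those with at least 20 MED1 tags.

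**Figure D3:**
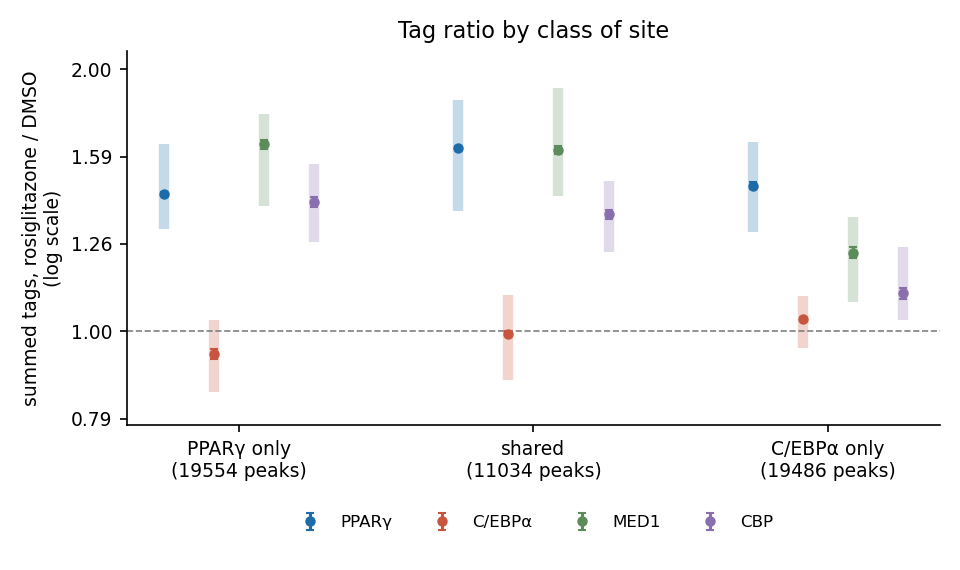
Ratio of summed tags, rosiglitazone over DMSO (vertical axis, log scale), for 4 factors at 3 classes of site (horizontal axis). Points carry exact 95% counting intervals and pale bars span the chromosomes; MED1 was 1.64 at PPARγ-only peaks and 1.23 at C/EBPα-only peaks.

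MED1 followed PPARγ from site to site, and CBP did not. PPARγ peaks with at least 20 PPARγ tags were placed in 5 groups by their PPARγ ratio, a comparison chosen after the values had been seen. From the group with the lowest PPARγ ratio to the highest, the MED1 ratio went from 0.756 (0.731 to 0.781) through 1.31 and 1.74 in the next 2 groups to 2.05 (2.01 to 2.08). CBP stayed between 1.40 and 1.49 over the same groups. C/EBPα moved in no single direction, with 1.26 in the lowest group, 0.810 in the middle group and 1.22 in the highest. Across single peaks with at least 20 tags of both factors, the log2 ratios of PPARγ and MED1 had a Spearman rho of 0.38 (0.34 to 0.42) and a Pearson r of 0.43 over 1669 peaks. PPARγ and CBP had a rho of -0.01 (-0.06 to 0.04) and an r of -0.01 over 1486 peaks, and PPARγ and C/EBPα a rho of 0.00 (-0.03 to 0.04) and an r of 0.08 over 2838. C/EBPα and MED1 had a rho of -0.26 (-0.32 to -0.20) and an r of -0.19 over 749 peaks. These are 4 of 6 pairs computed, and peaks are not independent replicates.

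**Figure D4:**
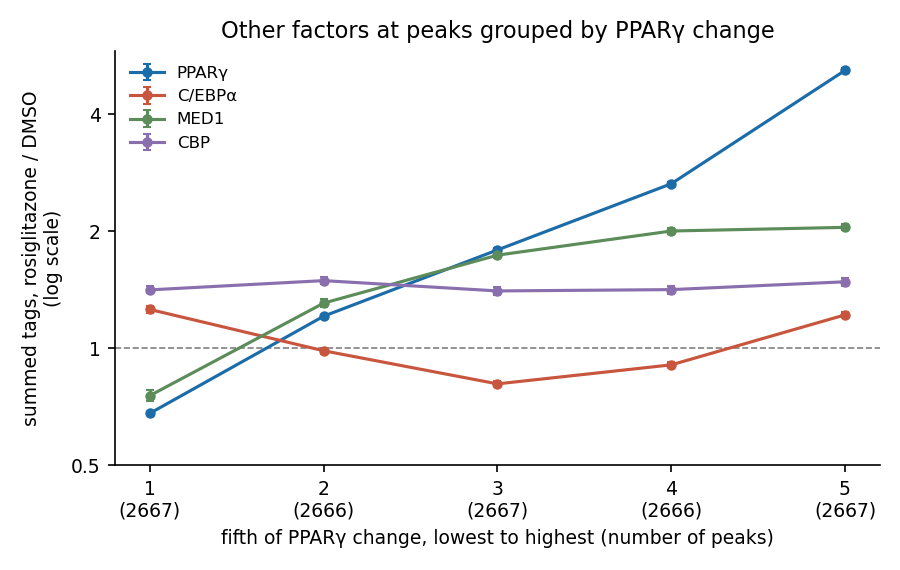
Ratio of summed tags, rosiglitazone over DMSO (vertical axis, log scale), of each factor at PPARγ peaks placed in 5 groups by PPARγ ratio (horizontal axis, lowest to highest), with exact 95% counting intervals. MED1 went from 0.756 to 2.05 with the PPARγ ratio, while CBP stayed between 1.40 and 1.49.

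At sites that both factors share, the MED1 ratio was higher in the PPARγ window. Each such site was counted once in the 186 bp window of its PPARγ peak and once in the 230 bp window of its C/EBPα peak. Where the centres lay under 20 bp apart, the MED1 ratio was 1.62 in the PPARγ window and 1.58 in the C/EBPα window, 1.03 times higher (1.02 to 1.04). Where they lay 150 bp or more apart, at 688 sites, the ratios were 1.72 and 1.45, 1.19 times higher (1.10 to 1.28). CBP gave 1.35 and 1.23 at those sites, 1.10 times higher (1.01 to 1.19), and no difference beyond its interval at shorter distances. PPARγ itself did not follow MED1. Its ratios were 1.63 and 1.61 under 20 bp, 1.01 times (1.01 to 1.01), but 1.62 and 1.70 at 150 bp or more, 0.954 times (0.901 to 1.01). C/EBPα gave 0.802 and 0.884 at 150 bp or more, 0.907 times (0.855 to 0.960). This comparison was also chosen after the values had been seen.

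**Figure D5:**
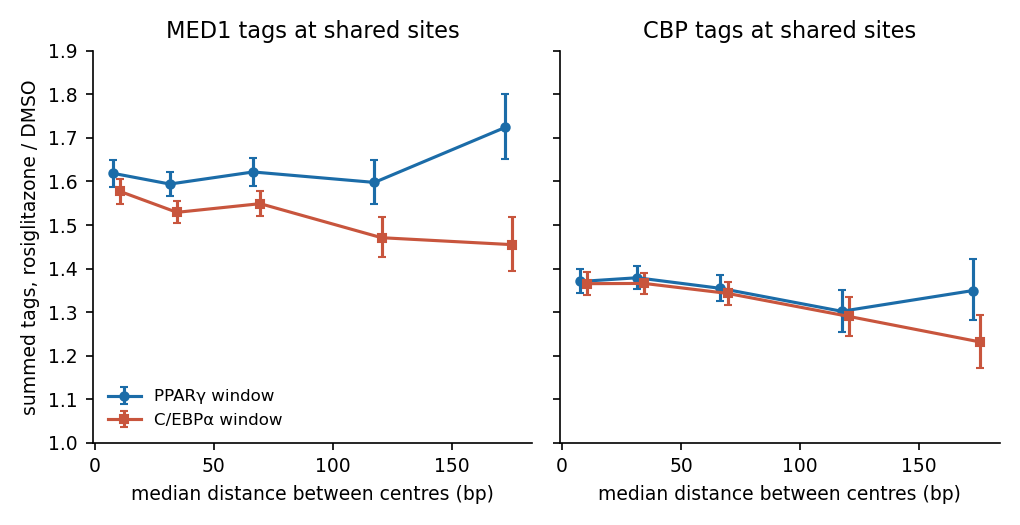
Ratio of summed tags, rosiglitazone over DMSO (vertical axis), at shared sites by the median distance between the PPARγ and C/EBPα centres in bp (horizontal axis), counted in the PPARγ window (blue circles) or the C/EBPα window (red squares), with exact 95% counting intervals. The MED1 lines part with distance, to 1.72 and 1.45 at a median of 174 bp.

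Peaks of both lists crowded together. Of the PPARγ peaks, 54.8% had another PPARγ peak within 10 kb, against 23.5% on average after uniform placement and 24.4% at most (one-sided p = 0.001, n = 30588 peaks, the smallest that 1000 placements can give). For C/EBPα the share was 50.2%, against 24.2% at most (p = 0.001, n = 30519 peaks). Clusters of at least 5 peaks numbered 477 for PPARγ and 345 for C/EBPα. The largest PPARγ clusters had 15 peaks each, on chromosome 11 from 98785618 to 98832902 and on chromosome 8 from 127344038 to 127400413. Their summed PPARγ ratios were 1.92 (1.62 to 2.28) and 1.89 (1.64 to 2.19), and their MED1 ratios 1.79 (1.36 to 2.36) and 1.95 (1.52 to 2.49). Regions of chromosome 19 and chromosome 8 were among the 5 largest clusters of both lists. The 12 PPARγ peaks on chromosome 19 from 47345019 to 47419303 had ratios of 2.86 (2.51 to 3.28) for PPARγ, 2.29 (1.82 to 2.88) for MED1 and 1.73 (1.33 to 2.24) for CBP. The 11 on chromosome 8 from 109638692 to 109675418 had 1.20 (0.984 to 1.47), 1.09 (0.676 to 1.74) and 0.866 (0.578 to 1.27), none beyond counting error. Another cluster on chromosome 8, of 12 C/EBPα peaks from 3211517 to 3260542, had 0.850 (0.706 to 1.02) for PPARγ and 0.867 (0.481 to 1.50) for MED1. Neither lay beyond counting error, but its C/EBPα ratio of 1.28 (1.08 to 1.53) did. The largest C/EBPα cluster had 18 peaks on chromosome 19 from 55854456 to 55926370, with a C/EBPα ratio of 1.36 (1.15 to 1.61) and a MED1 ratio of 0.891 (0.618 to 1.27). Uniform placement takes no account of where chromatin is open or can be mapped.

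RNA polymerase II occupancy, which the design also names, was not analysed here, and neither were gene lists near peaks.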

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

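The alternatives that use summed tags, scale to C/EBPα-only peaks, thin the libraries, drop high-background regions or the top 1% of peaks, or combine a choice with a 20-tag minimum, the 20-tag and centring alternatives for PPARγ, and those for odds ratios were chosen after seeing the data. No paired analysis was possible because each factor has 1 column per treatment and none names a replicate. For the same reason DESeq2, size factors, leaving out replicates and the 1.5-fold filter for PPARγ were not run, nor any alternative for RNA polymerase II or gene lists, which were not analysed here. Sharing, heights, clustering and the MED1 and CBP odds ratios of PPARγ-only against C/EBPα-only peaks kept their direction and their side of the threshold under every alternative run. For heights, the peak score was no separate check, since it nearly equalled the scaled pooled tags. Sharing of PPARγ peaks ranged from 28.6% (strongest 5000 of each list) to 41.8% (centres within 500 bp). Clustering within 5 and 25 kb covered 38.0% and 74.8% of PPARγ peaks. The odds ratios with at least 20 tags in total were 1.17 for MED1 and 1.24 for CBP.

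Median log2 ratios of PPARγ and C/EBPα shifted in size but not in sign. PPARγ, 0.50, was 0.38 with a pseudocount of 5, 0.82 with at least 20 tags and 0.61 from summed tags. C/EBPα, 0.0750, was 0.0589, 0.25 and 0.0184. MED1 and CBP, both 0.00, were 0.78 and 0.26 with at least 20 tags and 0.70 and 0.46 from summed tags. The C/EBPα ratio at shared peaks, 0.994 (0.987 to 1.00), did not differ from 1 beyond counting error. Without the top 1% of peaks it reversed to 1.02, so its side of 1 depended on those peaks. Without that 1%, PPARγ ratios were 1.41 at PPARγ-only, 1.60 at shared and 1.45 at C/EBPα-only peaks, MED1 1.58, 1.55 and 1.15, CBP 1.38 at PPARγ-only and 1.08 at C/EBPα-only peaks, and C/EBPα 1.05 at C/EBPα-only peaks.

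Counts of peaks at least 2-fold higher and lower depended most on the choices. With at least 20 tags, fewer peaks were counted: 5678 and 464 for PPARγ, 1670 and 441 for C/EBPα, 796 and 288 for MED1, and 207 and 133 for CBP. Thinning these to equal depth gave 5208 and 450, 714 and 532, 754 and 48, and 154 and 4. The minimum was applied again after thinning, which left 12526 of 13333 PPARγ, 4887 of 8934 C/EBPα, 1106 of 1896 MED1 and 429 of 1807 CBP peaks, so the effects of depth and of fewer peaks are not separated. Centring them on their median gave 2175 and 2283, 1140 and 882, 290 and 446, and 105 and 208. Scaling them to C/EBPα-only peaks gave 3124 and 1499 for PPARγ, 1559 and 519 for C/EBPα, 594 and 342 for MED1, and 144 and 167 for CBP. Over all peaks, PPARγ counts were 4767 and 4089 when centred and 4609 and 4595 when scaled, and scaling turned the MED1 balance to 7334 and 7510. A pseudocount of 5 gave 6271 and 546 for PPARγ, 3328 and 1554 for C/EBPα, 8073 and 4627 for MED1, and 5527 and 3407 for CBP, whose balance turned from 7234 and 7676. Centring the other factors on the median of all peaks changed no MED1 or CBP count, since that median was 0. Apart from the minimum, the cause was not tested. Depth limits MED1 and CBP most: 38.5% and 45.9% of PPARγ peaks held 0 tags in their rosiglitazone libraries.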

Other observations

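The tests by size of PPARγ ratio, by PPARγ tags at C/EBPα-only peaks, of the windows of the lists, and of PPARγ at C/EBPα-only peaks were chosen after the result had been seen.

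PPARγ peaks that were far lower in the rosiglitazone library held few tags of the other factors. Among the 13333 PPARγ peaks with at least 20 tags in the higher library, 54 were at least 8-fold lower. Of these, 1 was shared with C/EBPα, and 52 (96.3%, 87.3 to 99.5) held 5 or fewer tags in the 6 libraries of the other factors together. Of the 45 that were 4- to 8-fold lower, 31 (68.9%, 53.4 to 81.8) were as empty. Among the 369 peaks at least 8-fold higher, 28 (7.59%, 5.10 to 10.8) were that empty and 42.8% were shared. The median focus ratio, the authors' measure of how closely tags gather at the centre, was 0.931 in the first group and 0.836 in the last. The 54 peaks lay on 18 chromosomes. Of the 8934 C/EBPα peaks with at least 20 tags, 0 were at least 8-fold lower, and of 82 at least 8-fold higher, 2 were that empty. An artefact of the DMSO PPARγ library was not excluded, and no explanation for these peaks was tested.

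C/EBPα peaks without a listed PPARγ peak still differed with the PPARγ tags beneath them. In the 4872 such peaks with the fewest PPARγ tags, MED1 in rosiglitazone was 0.827 times DMSO (0.788 to 0.867) and C/EBPα 1.14 times (1.12 to 1.15). In the 4872 with the most, MED1 was 1.45 times (1.42 to 1.48) and C/EBPα 0.957 times (0.947 to 0.966). CBP went from 1.02 (0.980 to 1.06) to 1.16 (1.14 to 1.19). The PPARγ ratio itself hardly differed, with 1.46 (1.41 to 1.52) at the fewest and 1.49 (1.47 to 1.51) at the most PPARγ tags. The MED1 ratio therefore went with the amount of PPARγ tags at these peaks and not with the PPARγ ratio.

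MED1 tags were higher at PPARγ peaks by more than at C/EBPα-only peaks. Enrichment of the whole MED1 rosiglitazone library by 1 factor, the same at all peaks, is argued against by 2 odds ratios at equal total tags. The first was 1.27 (1.24 to 1.31), and 1.17 (1.11 to 1.24) with at least 20 tags in total. The second, within C/EBPα-only peaks and their own windows, was 1.49 (1.39 to 1.61) for most against fewest PPARγ tags. It was a condition added after both were seen. An enrichment that differs with the share of background tags stays open. Most peaks held few MED1 tags, so equal total tags need not mean equal MED1 occupancy. A few very high peaks are argued against by the 109% of the log2 difference kept without the top 1%. The unlike windows of the lists stay open: shared against C/EBPα-only sites, all counted in C/EBPα windows, gave 1.05 (1.02 to 1.09), and 0.982 (0.931 to 1.04) with at least 20 tags. That comparison was run first and left the question undecided. One made afterwards, of the same shared sites between windows, gave 1.05 (1.04 to 1.06) where PPARγ-only and C/EBPα-only peaks differ by 1.33. Windows therefore account for little of it only if unshared sites behave alike. The 1.05 pools sites with a median of 41 bp between centres, and it grew with distance to 1.19 (1.10 to 1.28) at 150 bp or more. Recruitment of MED1 by ligand-bound PPARγ may contribute, a hypothesis that 1 library per treatment cannot test against the spread between cultures.

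PPARγ tags were higher in the rosiglitazone library at most peaks. Enrichment of that library by 1 factor, the same at all peaks, is argued against for the differences between peaks. These differences followed those of MED1, a separate pair of libraries, with a rho of 0.38. Those of CBP and C/EBPα did not follow, with a rho of -0.01 and 0.00. An enrichment that differs with the share of background tags was not tested. For the mean, such a factor and higher occupancy cannot be told apart. The ratio was 1.47 at C/EBPα-only peaks and 1.44 at PPARγ-only peaks, but 1.63 at shared peaks. At the 4872 C/EBPα-only peaks with the fewest PPARγ tags it was 1.46 (1.41 to 1.52). These values met neither the outcome set for a common factor nor the one set against it. That outcome was reworded after the value at C/EBPα-only peaks was known, and tags outside peaks were not analysed here. More PPARγ on chromatin, also at weak sites, and a better immunoprecipitation may both contribute.

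On chromosome 10 between 117147005 and 117540658, some peaks of every antibody were very high. Others there were not. The PPARγ-only peak from 117514711 to 117514897 held 10.55 and 9.15 units of PPARγ and 0 and 2.55 of C/EBPα in DMSO and rosiglitazone. The genome medians of both treatments together at PPARγ-only peaks were 21.03 and 6.03. The bounds of this region are edges of the highest C/EBPα peaks there. Its 1 Mb region had been marked as high background by C/EBPα tags at PPARγ-only peaks. Extra copies of the region in these cells stay open, as unshared peaks there held 13.3 and 3.97 times the genome median of the other factor's tags. The 13.3 is for C/EBPα tags at PPARγ-only peaks, so it is not independent of that marking. At the 12 PPARγ-only peaks PPARγ was 6.99 (1.98 to 16.7), MED1 12.1 (4.54 to 44.0) and CBP 6.42 (2.96 to 50.9) times its median, and at the 14 C/EBPα-only peaks C/EBPα was 2.57 (1.47 to 4.96), CBP 4.71 (2.67 to 7.53) and MED1 13.9 (11.1 to 20.6), where every MED1 and CBP fold rests on a genome median of 2 tags per peak. A dense cluster of regulatory sites with normal copy number cannot be told apart from copies, since the lower bound of the smaller fold was 2.58, short of the 3 set beforehand, a bound asked of both explanations only after the values were seen. Input chromatin was not analysed here, and no other explanation was tested.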
